A study of Zea mays with 12 samples.

How the data were processed

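RNA from developing maize embryos was measured on 12 one-colour Affymetrix maize arrays. The samples came from the inbred lines B73 and Mo17 and from both reciprocal hybrids, with 3 biological replicates in each of the 4 groups, all at 19 days after pollination. Per the labels' protocols, the plants were grown in a field, the embryos of replicates with the same number were collected on 1 date, and the 3 replicates of a genotype stand for different dates. Groups and replicate numbers were taken from the labels. A cross is written with the seed parent first, which is the usual convention and is not spelled out in the labels. The replicates are separate biological samples per the labels.

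The values used are the deposited probe set signals, linear intensity values for 17734 probe sets on 12 arrays in 1 table. The submitters' processing notes name MAS5, with no version. A probe set is a group of short probes designed against 1 transcript sequence, and its signal summarises their brightness. No normalization between arrays is recorded in the sources used here, and the deposited intensity values of the arrays differed in scale: the array medians ran from 192.1 to 313.8, a ratio of 1.634. Detection calls were not used here, so a low signal cannot be sorted into measured and background, and differences that rest on signals near the low end are uncertain in size. For large differences against a dim group the fold is therefore also given after a floor was set at the 25th percentile of the normalized values, 27.6 signal units. The number of arrays limits the precision.

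The 113 control probe sets were left out, which leaves 17621 probe sets, and no filter on dim ones was set. Signals were put on the log2 scale and quantile normalized between arrays. The design had taken the deposited values to be normalized already. The array medians showed that they were not, so quantile normalization, planned as an alternative, became the main setting before any test was run, and the values as deposited became an added alternative. Some differences in array brightness could in principle have come from the genotypes, and quantile normalization removes any such overall difference.

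Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 8 residual degrees of freedom and a median of 5.1 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 17621 probe sets, with a threshold of 0.05. Differences are given on the log2 scale with limma's standard error (SE). Group levels are mean log2 signals ± SD over 3 arrays. Hybrids were compared with the mid-parent, the arithmetic mean of the linear group means of both inbreds, since outputs of 2 alleles add on the linear scale. The standard error of that comparison came from the delta method. A hybrid level outside the parental range needed differences of one sign from both inbreds, and the larger of the limma p-values was adjusted. The dominance to additive ratio, d/a, is the hybrid level minus the mid-parent divided by the half-difference between the inbreds, on the linear scale. It is 0 at the mid-parent, 1 at the higher inbred and -1 at the lower inbred, and it was computed for probe sets that differed between the inbreds by at least 1.5-fold, without a test across genes.

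Gene names came from the platform annotation table. It gave 1 gene for 1452 probe sets and several genes for 1, and the other 16168 probe sets are unnamed here. The 1452 probe sets stand for 1108 genes, of which 1060 were matched by gene ID to the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0. That table was used for names only, since no coordinates of the probes were used. Of the genes, 971 had a name other than a locus number, and 222 had at least 2 probe sets. For gene lists each gene was represented by its probe set with the highest mean.

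Of 20 gene lists fixed before the data were examined, 17 had members on the array. Names alone were searched, since no gene descriptions were used, and matches that plainly belonged to other genes were removed before testing. The lists covered zeins, other endosperm genes, embryo globulins with oleosins and LEA proteins, photosynthesis, cytosolic ribosomal proteins, histones, DNA replication and cell cycle, heat shock proteins and chaperones, glutathione transferases, cytochrome P450s with benzoxazinoid synthesis, defence proteins, flavonoid and lignin synthesis, lipid synthesis, glycolysis and fermentation, peroxidases with catalases and superoxide dismutases, developmental transcription factors, and DNA and chromatin modification. Lists of organelle-encoded genes, of ubiquitin and the proteasome, and of transposons matched 0 genes and gave no result. The 14 lists with at least 5 genes were tested with limma's camera at a preset inter-gene correlation of 0.01 in 3 contrasts, adjusted over 42 tests, and again with an estimated correlation. In the mid-parent contrast camera used the log2 mid-parent.

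Genes named in the text follow a rule fixed in advance. Each gene is represented by its probe set with the highest mean. Per comparison the rule takes the 10 named genes with the largest change in each direction among those past the threshold whose replicates did not overlap, or all of them where there are fewer, plus the 4 members of each list with the smallest p between the inbreds, plus the 2 probe sets with the largest change in each direction whatever their annotation. Any other gene or probe set named was picked after its values had been seen.

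The shared collection date pairs the samples by number. As a check, deviations from the group means were correlated between arrays. Over all probe sets the median correlation was 0.006 for the 18 pairs of arrays of one date and -0.005 for the 36 pairs of different dates. With the 50 percent of probe sets of lower signal left out it was 0.134 for one date, with 10 of 18 pairs above 0.1, and -0.092 for different dates. No 2 arrays held identical values.

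The alternatives were median centring, the values as deposited, leaving out the lowest 33.3 or 50 percent of the probe sets by mean signal, the floor, the replicate number as a block, a fit of only the groups compared, eBayes without the trend, array weights, leaving out each array in turn, a log2 mid-parent, a fit on linear values, other minimum folds, all probe sets of a gene, and an arithmetic statistic for the lists. The last one and the values as deposited were chosen after seeing the data.

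The scripts were tested on simulated data with 17621 probe sets. Separate sets of 200 were changed between the inbreds, between the reciprocal hybrids, and in both hybrids away from the inbreds. The last set served for the mid-parent and the parental range, and its inbreds were equal. Its recoveries therefore do not describe probe sets that differ between the inbreds. At 1.5-fold, 91 of the 200 were recovered between the inbreds, 65 between the reciprocal hybrids, 99 against the mid-parent and 78 outside the parental range. At 2-fold, 112 of the 200 were recovered between the inbreds, 123 between the reciprocal hybrids, 147 against the mid-parent and 131 outside the parental range. At 4-fold these counts were 134, 148, 169 and 152. False calls numbered at most 5 at 1.5-fold, 11 at 2-fold and 7 at 4-fold, except against the mid-parent at 4-fold, where there were 25, of which 20 were lower. The adjustment of p depends on the share of probe sets that change, and in the data 6321 were called between the inbreds. The simulated recoveries and false calls between the inbreds therefore do not describe that comparison. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15.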

Results

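Maize embryos of 2 inbred lines, B73 and Mo17, and of the hybrids B73xMo17 and Mo17xB73 were profiled at 19 days after pollination. B73 and Mo17 are widely used parents of hybrid maize. The hybrids carry the same pair of nuclear genomes and differ in which line was the seed parent. The title of the series gives the question: whether genes expressed differently by the inbreds are expressed additively, at the mean of both parents, in the hybrids. Each group had 3 arrays. The median deposited signal was lowest in Mo17xB73 replicate 1 (192.1) and highest in B73xMo17 replicate 2 (313.8). Before normalization, log2 signals correlated between 0.969 and 0.974 within a group and between 0.915 and 0.919 across B73 and Mo17 arrays.

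The inbreds differed at 35.9% of the probe sets. Transcripts of HRGP, a hydroxyproline-rich cell wall protein, and of TPS9 were abundant in B73 and near the low end of the array in Mo17. Those of dzs18, a delta zein storage protein, and his2b5, a histone H2B, also gave far higher signals in B73, against Mo17 signals above that end. Genes higher in Mo17 included pep7 and the YABBY transcription factor yab14. HRGP measured 10.71 ± 0.40 in B73 and 0.33 ± 2.10 in Mo17 (mean log2 signal ± SD, n = 3), a difference of 10.38 ± 0.70 (SE; limma adjusted p = 5.1e-08). With the floor its fold fell from 1331 to 60.8. TPS9 differed by 9.94 ± 0.85 (adjusted p = 5.8e-07), or 151-fold with the floor. dzs18 was 132-fold higher in B73 (log2 difference 7.04 ± 0.10, adjusted p = 1.5e-14; its B73 level of 13.59 is near the top of the scale, where folds can be understated), his2b5 104-fold (6.70 ± 0.12, adjusted p = 1.4e-13) and the small heat shock gene hsp18a 14.6-fold (3.87 ± 0.18, adjusted p = 1.2e-09). In the other direction pep7 was 10.7-fold higher in Mo17 (-3.42 ± 0.09, adjusted p = 7e-12) and yab14 6.97-fold (-2.80 ± 0.17, adjusted p = 2e-08).

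Other genes among the largest differences had a dim partner. LOB21, piip2, saf1, gss1 and sig3 were higher in B73 by 6.99, 5.20, 4.81, 4.57 and 4.09 on the log2 scale, and by 3.04, 1.84, 3.5, 2.81 and 2.74 with the floor. sig3 and sig1 encode sigma factors of the plastid RNA polymerase, and sig1 ran the other way, at -3.79 (-1.10 with the floor). GR2b stood at -3.64 (-1.23 with the floor), the tonoplast aquaporin gene tip2a at -2.96 (-2.50) and the MADS-box gene m20 at -2.59 (-2.40). bap-3a, bde1, sat1 and nthr3 were called higher in Mo17 from signals that both lay near or below the floor. With it their differences were -0.05, 0.00, 0.00 and -0.03. The widest differences toward Mo17 were those of 2 probe sets unnamed here, at -10.80 ± 0.10 (-7.64 with the floor) and -10.78 ± 0.31 (-7.06 with the floor). The ID of the first shares its cluster number with that of his2b5, which ran the other way. Toward B73 they were those of HRGP and of another probe set of dzs18, at 10.09 ± 0.80 (8.63 with the floor).

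Single genes of seed storage and endosperm differed between the lines. Of 7 zein genes 3 were higher in B73 and 0 lower (3 adjusted over the list alone): dzs18, z1C2 (1.22 ± 0.24) and z1C1_20 (0.31 ± 0.07), the last lost with median centring (0.19, adjusted p = 0.195) and with the values as deposited. Over the 4 groups z1C1_20 lay between 12.84 and 13.19 and z1D_2 between 12.94 and 13.41, where the highest normalized value was 14.0. Of 23 other endosperm genes 8 were higher in Mo17 and 1 in B73 (9 adjusted over the list alone). Those higher in Mo17 included genes of the basal transfer layer, the endosperm tissue that takes up nutrients from the mother plant: bap1-b (-1.84 ± 0.19), meg2 (-1.69 ± 0.20) and bap2 (-1.92 ± 0.27). The gene higher in B73 was o2, the transcription factor Opaque2 that controls zein genes (2.82 ± 0.23). A dimmer probe set of o2 stood at 0.70 and was not called (limma adjusted p = 0.19). Of 9 embryo globulin, oleosin and LEA genes 5 were higher in B73 and 1 in Mo17 (6 adjusted over the list alone). emb5 (2.26 ± 0.29), glb3 (1.26 ± 0.14) and dhn2 (0.70 ± 0.14) were higher in B73 and glb2 (-1.27 ± 0.12) in Mo17.

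Metabolic and stress gene groups were divided between the lines. Glutathione transferases split evenly, 7 higher in each line of 31 (15 adjusted over the list alone), with gst6 (2.28 ± 0.14) and gst3a (1.19 ± 0.12) higher in B73 and GST38 (-0.93 ± 0.14) and gst17 (-0.47 ± 0.07) higher in Mo17. Of 12 heat shock genes hsp18a alone was higher in B73, and 4 were higher in Mo17 (5 adjusted over the list alone), among them hsp101 (-2.18 ± 0.22), hsp18f (-0.77 ± 0.18) and hsp22 (-1.13 ± 0.36). Of 14 glycolysis and fermentation genes 3 were higher in B73 and 1 lower (4 adjusted over the list alone): the sucrose synthase gene sus2 (1.32 ± 0.10), the alcohol dehydrogenase adh2 (0.64 ± 0.08), the pyruvate decarboxylase pdc1 (2.17 ± 0.31) and, lower, gpc1 (-0.17 ± 0.05). A dimmer probe set of pdc1 stood at -0.14 (limma adjusted p = 0.85) and one of gpc1 at -2.57 (limma adjusted p = 3.6e-09). Of 8 peroxidase, catalase and dismutase genes 2 were higher in B73, Sod4A (1.64 ± 0.09) and CAT3 (2.05 ± 0.57, and 1.08 with the floor), and apx2 was lower (-0.59 ± 0.14; 3 adjusted over the list alone). In the benzoxazinoid and P450 list of 4, igl1 was higher in B73 (1.05 ± 0.11) and bx6 (-0.87 ± 0.06) and d3 (-0.65 ± 0.20) in Mo17 (3 adjusted over the list alone). Of 5 flavonoid and lignin genes fht1 was higher in B73 (2.10 ± 0.25) and BM1 in Mo17 (-0.79 ± 0.15; 2 adjusted over the list alone), and of 4 lipid genes fad7 (0.38 ± 0.10) and FAD8 (-1.18 ± 0.24) went opposite ways (2 adjusted over the list alone). Of 8 defence genes prp2 was higher in B73 (1.03 ± 0.17) and lox1 in Mo17 (-1.07 ± 0.40, and -0.31 with the floor; 1 adjusted over the list alone). A dimmer probe set of lox1 stood at -0.73 and was not called (limma adjusted p = 0.64).

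Genes of growth and gene regulation also differed, mostly by small amounts. Of 18 cytosolic ribosomal protein genes 3 were higher in each line (6 adjusted over the list alone), with rpl30 (1.13 ± 0.10), rps13 (0.80 ± 0.10) and rpl29 (0.36 ± 0.08) higher in B73 and rpl39 (-0.58 ± 0.06) in Mo17. Of 4 histone genes only his2b5 differed by its brightest probe set (1 adjusted over the list alone). A dimmer probe set of cenH3 was called at -0.91 (limma adjusted p = 0.016). Of 8 replication and cell cycle genes 3 were higher in Mo17 and 0 in B73 (4 adjusted over the list alone): pcna2 (-0.61 ± 0.09), pcna1 (-0.33 ± 0.11) and cyc3 (-0.26 ± 0.09). Of 33 genes listed as developmental transcription factors 7 were higher in B73 and 4 in Mo17 (11 adjusted over the list alone), with rs2 (1.55 ± 0.16), hox1a (0.76 ± 0.10) and hxa103 (0.56 ± 0.07) on one side and hox3 (-0.91 ± 0.13) on the other. hxa103 was in this list only through its synonym MYBR106, and its function was not checked. Of 39 chromatin genes 10 were higher in B73 and 4 in Mo17 (14 adjusted over the list alone), including the methyl-binding proteins mbd108 (0.39 ± 0.07) and mbd101 (0.35 ± 0.06), the SET-domain gene sdg118 (0.38 ± 0.08) and the Polycomb gene fie1 (1.10 ± 0.22). None of the 13 photosynthesis genes passed the limma threshold over all probe sets or over the list alone, while 2 had an unadjusted p below 0.05. None of the 14 lists tested stood apart from other genes between the inbreds, with the smallest adjusted p for the zeins (0.0728). Median and mean differed in sign for the transcription factors (0.07 and -0.13, camera direction up), the chromatin genes (-0.03 and 0.03, up), the flavonoid genes (-0.11 and 0.07, down), the lipid genes (0.11 and -0.15) and the histones (-0.02 and 1.62), the last 2 not tested as lists. Calls lost without single arrays were those of cyc3, d3, gpc1, hsp22 and pcna1 (each without B73 replicate 1 or 2, among others, with adjusted p up to 0.148, 0.0902, 0.0886, 0.0955 and 0.125), fad7 (0.0569 without B73 replicate 2) and lox1 (9 of the 12 arrays, up to 0.191). The call of lox1 was also lost with the replicate number as a block (adjusted p = 0.053). With the values as deposited the calls of pcna2, pcna1, cyc3, mbd108, mbd101, sdg118, hxa103, rpl29, rpl39, gpc1, gst17, hsp18f, apx2, BM1, d3, fad7 and lox1 were lost.

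In all, limma called 6321 of 17621 probe sets between the inbreds, 2889 higher in B73 and 3432 higher in Mo17, with 2361 of them at least 2-fold apart (1287 and 1074). With the values as deposited the count fell to 2963 and the split to 1813 and 1150. Of the 222 genes with at least 2 probe sets, 123 had a call. In 43 of them (35.0%) another probe set was called in the same direction, in 10 in the opposite one, and in 70 only 1 probe set was called. In 29 genes all probe sets were called in one direction, 12 toward B73 and 17 toward Mo17.

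**Figure D1:**
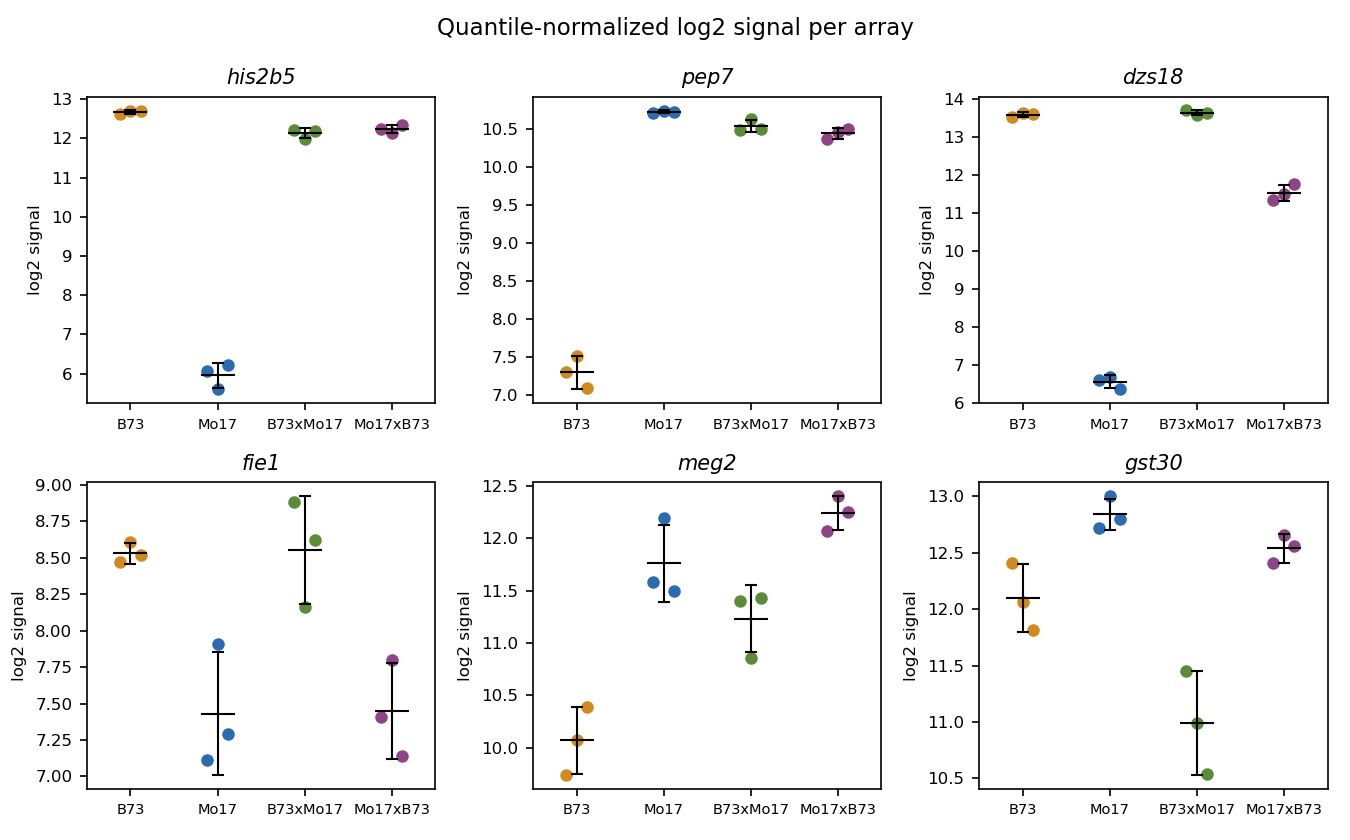
Quantile-normalized log2 signal (vertical axis, log2 units, scaled to each gene) of 6 genes on each of 12 arrays, with 3 points per genotype, the group mean as a long line and 1 SD as error bars. Hybrid arrays lie close to the higher inbred on this log scale for his2b5 and pep7, and the hybrids part from each other for dzs18, fie1, meg2 and gst30.

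Few probe sets were called as departing from the mid-parent in the hybrids, which does not show that few transcripts departed. Above it were betl3, a gene of the basal endosperm transfer layer (1.78-fold), glb2, an embryo globulin (1.63-fold), pep7 (1.56-fold) and the cellulose synthase genes CesA-4 (1.47-fold) and CesA-9 (1.23-fold). Below it was mir3 (LOC100037824), a cysteine protease (1.87-fold). Outside the naming rule, a probe set of gpc1 was called 0.82 ± 0.11 above it (adjusted p = 0.0049) and one of CDPK at -0.28 ± 0.04 (adjusted p = 0.0083), both lost with the values as deposited and without the eBayes trend, and neither was the brightest probe set of its gene (that of gpc1 stood at 0.02, adjusted p = 0.83). The level of betl3 was 8.21 ± 0.19 in B73, 8.38 ± 0.31 in Mo17, 9.07 ± 0.37 in B73xMo17 and 9.20 ± 0.14 in Mo17xB73 (mean log2 signal ± SD, n = 3), and the hybrid mean lay 0.83 ± 0.13 (SE; limma adjusted p = 0.013) above the mid-parent. glb2 lay 0.71 ± 0.09 above it (adjusted p = 0.0049), pep7 0.64 ± 0.08 (adjusted p = 0.0049), CesA-4 0.55 ± 0.11 (adjusted p = 0.039) and CesA-9 0.30 ± 0.06 (adjusted p = 0.045), while mir3 (LOC100037824) stood at -0.90 ± 0.18 (adjusted p = 0.04). A dimmer probe set of CesA-4 stood at 0.49 and was not called (limma adjusted p = 0.46). The largest departures were those of 4 probe sets unnamed here. Zm.12.1.S1_at lay 1.75 ± 0.13 above the mid-parent, with levels of 6.0 ± 0.39 in B73, 11.53 ± 0.12 in Mo17, 13.04 ± 0.17 in B73xMo17 and 11.59 ± 0.15 in Mo17xB73. The second probe set above it stood at 1.47 ± 0.28, and those below at -2.93 ± 0.49 (-1.11 with the floor) and -1.88 ± 0.31 (-0.03 with the floor). Without B73xMo17 replicate 3, among other arrays, the calls of CesA-4 (adjusted p up to 0.141), CesA-9 (up to 0.123), mir3 (LOC100037824) (up to 0.123) and the second probe set above (up to 0.099) were lost, and that at -2.93 was lost without Mo17 replicate 2 or 3 (up to 0.0817). betl3, glb2 and pep7 kept their calls without any single array and lost them with the values as deposited and without the eBayes trend, betl3 also with the floor.

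Against the mid-parent limma called 93 of 17621 probe sets, 47 above and 46 below, and 2169 had an unadjusted p below 0.05. The means of 27 of the 47 and 32 of the 46 lay outside the range of both parental means. For B73xMo17 alone 139 were called (55 above, 84 below) and for Mo17xB73 alone 93 (60 above, 33 below). The counts and the direction split rested on single arrays, the scaling, the floor, the variance model and the definition of the mid-parent. Median centring gave 30 above and 154 below for the hybrid mean, 31 and 153 for B73xMo17 and 32 and 81 for Mo17xB73, and the values as deposited gave 8 calls for the hybrid mean (4 and 4), 2 above and 17 below for B73xMo17, and 4 and 7 for Mo17xB73. With the floor 29 were above and 90 below for the hybrid mean, 30 and 83 for B73xMo17, and 18 and 60 for Mo17xB73. Against the log2 mid-parent, which is lower by construction, 763 were above and 118 below (647 and 164 for B73xMo17, 600 and 93 for Mo17xB73), and without the eBayes trend 4 calls remained for the hybrid mean, 21 for B73xMo17 and 0 for Mo17xB73. The count for the hybrid mean was 47 without B73 replicate 2, 41 without Mo17 replicate 3, 58 without B73xMo17 replicate 3, 55 without Mo17xB73 replicate 1, 48 without its replicate 3, and 153 with the replicate number as a block.

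In limma's camera test against the log2 mid-parent the zeins (7 genes, median 0.24, adjusted p = 5.57e-05), the other endosperm genes (23 genes, median 0.30, adjusted p = 0.000106) and the embryo globulins, oleosins and LEA proteins (9 genes, median 0.24, adjusted p = 0.00301) were shifted up. None of these calls held with an estimated correlation, where the zeins had adjusted p = 0.207, the other endosperm genes adjusted p = 0.322 and the embryo proteins adjusted p = 0.614. With a statistic built on the arithmetic mid-parent and the preset correlation, the adjusted p-values were 0.000756, 6.12e-06 and 0.000569. Gene by gene, 0 of 7 zeins passed limma's threshold (2 with an unadjusted p below 0.05), 1 adjusted over the list alone. Of the 23 other endosperm genes betl3 alone did (6 adjusted over the list alone, all higher). The 10 basal layer genes among them ran from -1.05 (ebe1) to 0.83 (betl3) and the others from -0.11 (rip2) to 0.97 (ESR1c1). Of the 9 embryo genes glb2 alone passed (2 adjusted over the list alone). Among glutathione transferases gst30 was below the mid-parent (-0.75, adjusted p = 0.029), a call lost without Mo17 replicate 2 or 3, among other arrays (up to 0.077). Each gene being represented by its brightest probe set, the other 13 lists with members had 0 genes past limma's threshold over all probe sets, with between 0 and 7 genes a list at an unadjusted p below 0.05. Adjusted over the list alone there were 2 for the glutathione transferases, 2 for the histones (1 higher, 1 lower), 1 lower each for the glycolysis, peroxidase and flavonoid lists, and 0 for the ribosomal, photosynthesis, replication, heat shock, P450, defence, lipid, transcription factor and chromatin lists. Median and mean against the log2 mid-parent differed in sign for the heat shock genes (-0.03 and 0.07, camera direction up), the peroxidases (-0.01 and 0.04, up), glycolysis (0.01 and -0.02, up) and the flavonoid genes (0.03 and -0.09, down), and for the P450 genes (0.04 and -0.10), the histones (-0.04 and 0.66) and the lipid genes (0.02 and -0.003), which were not tested as lists.

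Across the 3766 probe sets that differed between the inbreds by at least 1.5-fold, hybrid levels clustered around the mid-parent. The median d/a was -0.08, with quartiles of -0.33 and 0.16, and 77.6% of probe sets lay within 0.5 of the mid-parent. Only 1.83% lay beyond the higher inbred and 1.41% beyond the lower one. B73xMo17 had a median of -0.08 with 70.7% within 0.5 of the mid-parent, and Mo17xB73 a median of -0.09 with 73.7%. Over the 6 hybrid arrays taken singly the SD of the median was 0.008 and that of the share 2.91 percentage points. The single arrays had lower shares, from 61.5% to 67.9%, and all were set against the same inbred means. These SDs therefore do not give the uncertainty of the 77.6% or of the median for both hybrids. The 1931 probe sets higher in B73 had a median of -0.006 (82.4% within 0.5) and the 1835 higher in Mo17 a median of -0.16 (72.5%), a difference that was not tested. On the log2 scale, where the mid-parent is lower, the median was 0.18 and the share 68.7%. Probe sets that may mark sequence differences under the probes were not set apart, so d/a values near 0 need not reflect transcript levels alone.

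**Figure D2:**
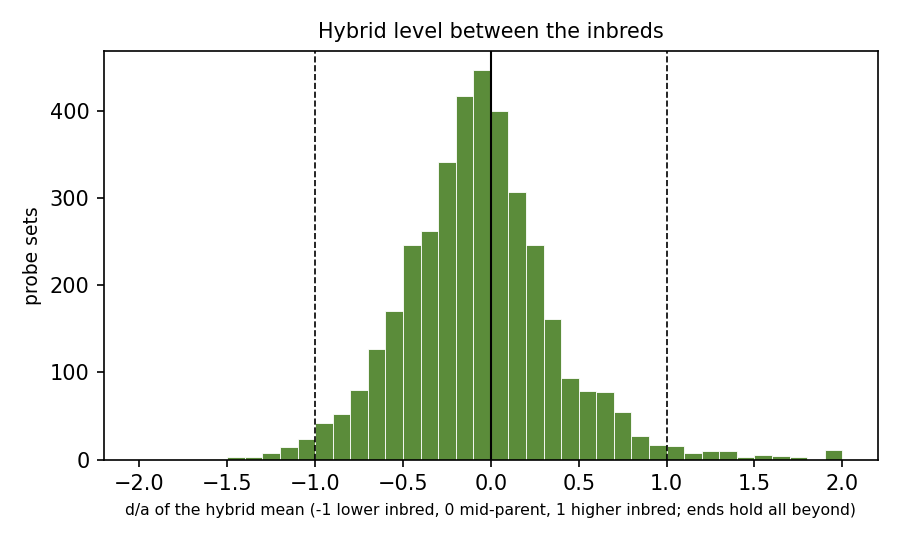
Number of probe sets (vertical axis) by d/a of the mean of both hybrids (horizontal axis, no unit), for the 3766 probe sets at least 1.5-fold apart between the inbreds. The solid line marks the mid-parent and the dashed lines the inbreds, and 77.6% of probe sets lie within 0.5 of the mid-parent.

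Set against each inbred, the hybrids differed from B73 at 2879 probe sets (1455 higher, 1424 lower) and from Mo17 at 4049 (1965 higher, 2084 lower). For B73 the split moved to 1224 higher and 1567 lower with median centring and to 541 and 375 with the values as deposited. For Mo17 it moved to 1775 higher and 3231 lower with median centring and to 1025 and 300 with the values as deposited. The values as deposited gave counts of 916 for B73 and 1325 for Mo17. The comparisons share the hybrid arrays, and whether they differ in size was not tested. No probe set passed limma's threshold for a hybrid level outside the parental range. At an unadjusted p below 0.05 there were 179. The count was 1 when only the groups compared were fitted and 1 without B73 replicate 2.

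Between the reciprocal hybrids single genes of several kinds differed. Higher in B73xMo17 were dzs18 (4.30-fold), the permease gene LPE1 (2.69-fold), fie1 (2.15-fold), a Polycomb gene known as maternally expressed in endosperm, the auxin synthesis gene yuc (1.90-fold) and the globulin gene glb3 (1.71-fold). Higher in Mo17xB73 were the zein gene z1C1_12 (3.22-fold), sfp1 (3.09-fold), the glutathione transferase genes gst30 (2.93-fold) and gst2 (2.56-fold), the basal layer genes bap1-b (2.52-fold), bap-1a (2.37-fold) and meg2 (2.01-fold), and opr5 (2.35-fold) and opr1 (1.98-fold), of a family of reductases that includes jasmonate synthesis enzymes. dzs18 differed by 2.11 ± 0.10 (limma adjusted p = 2.9e-07; B73xMo17 at 13.64, near the top of the scale), and 2 further probe sets of it were called in the same direction. fie1 differed by 1.10 ± 0.22 (adjusted p = 0.039), with 8.55 ± 0.37 in B73xMo17, 7.45 ± 0.33 in Mo17xB73, 8.53 ± 0.07 in B73 and 7.43 ± 0.42 in Mo17 (mean log2 signal ± SD, n = 3). gst30 differed by -1.55 ± 0.19 (adjusted p = 0.0019) and z1C1_12 by -1.69 ± 0.19 (adjusted p = 0.0014). Smaller differences passed the threshold for S6K (0.76 ± 0.15), plt2 (0.45 ± 0.09), ubc7 (0.35 ± 0.06) and phi1 (0.29 ± 0.06), and lox1 was called at -1.93 ± 0.40, or -0.34 with the floor. A dimmer probe set of lox1 stood in the opposite direction at 0.49 and was not called (limma adjusted p = 0.92). The 2 largest differences in each direction, of probe sets unnamed here, were -3.80 ± 0.67, -3.70 ± 0.67, 3.68 ± 0.62 and 3.17 ± 0.61, and all were within 0.01 of 0 with the floor and lost their calls without B73xMo17 replicate 2 or 3, among other arrays (adjusted p up to 0.117).

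Limma called 153 of 17621 probe sets between the reciprocal hybrids, 64 higher in B73xMo17 and 89 higher in Mo17xB73, with 77 at least 2-fold apart (25 and 52). The count was 72 without B73xMo17 replicate 2, 61 without its replicate 3, and 95, 57 and 51 without Mo17xB73 replicates 1, 2 and 3. It was 39 without the eBayes trend, 76 with the floor and 42 with the values as deposited. Without the trend the split was 16 higher in B73xMo17 and 23 lower, with the floor 40 and 36, and with the values as deposited 20 and 22. Of the 23 genes and probe sets named for this comparison 7 kept their call without any single array, and dzs18, LPE1, z1C1_12 and gst30 kept it under every alternative run. The calls of fie1 (lost in 8 of 12 cases, adjusted p up to 0.164), meg2 (7, up to 0.137), glb3 (5, up to 0.127), yuc (5, up to 0.112), gst2 (4, up to 0.0819), ubc7 (4, up to 0.114), S6K (8, up to 0.153), lox1 (9, up to 0.166), and opr1, opr5, phi1 and plt2 (10 each, up to 0.199) were each lost without B73xMo17 replicate 3, among other arrays.

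By group, the glutathione transferases were lower in B73xMo17 than in Mo17xB73 (31 genes, median -0.19, camera adjusted p = 0.002), a call that was lost with an estimated correlation (adjusted p = 0.105). Of the 31 genes gst30 and gst2 passed limma's threshold (4 adjusted over the list alone, all lower). Of the other endosperm genes 2 of 23 were lower in B73xMo17, bap1-b and meg2 (5 adjusted over the list alone), and the list itself was not called (median -0.12, adjusted p = 0.177). With the values as deposited that median was 0.02, against a shift of 0.12 over all probe sets. Of the zeins dzs18 was higher and z1C1_12 lower (3 adjusted over the list alone). Of the 9 embryo genes glb3 was higher (2 adjusted over the list alone), of the 39 chromatin genes fie1 (1 adjusted over the list alone), and of the 8 defence genes lox1 was lower (2 adjusted over the list alone), with a list median of -0.62 and an adjusted p of 0.0644. The other 11 lists had 0 genes past limma's threshold over all probe sets, with between 0 and 3 genes a list at an unadjusted p below 0.05. Adjusted over the list alone there were 1 lower for the P450 list, 1 higher for the peroxidases and 0 for the other lists. Median and mean differed in sign for the zeins (-0.04 and 0.01, camera direction down), photosynthesis (-0.03 and 0.08, down) and the flavonoid genes (-0.01 and 0.01, up), and camera's direction for the peroxidases was up against a median of -0.04.

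The reciprocal difference leaned toward the seed parent. Of the 153 probe sets called, 114 were also called between the inbreds, where 54.9 would be shared by independent lists of these sizes. In 105 of the 114 (92.1%) the cross whose seed parent was the higher inbred was the higher cross, as for dzs18, fie1, bap1-b and meg2. This compares the crosses with each other and does not place each hybrid nearer its seed parent. Over all 6321 probe sets called between the inbreds the share was 65.3%. By collection date it was 58.4%, 64.9% and 60.5%. Across these probe sets, which are not independent replicates, the reciprocal and the inbred differences correlated with Pearson's r = 0.276 and Spearman's rho = 0.34. Exchanging the labels of the crosses within dates gives 4 assignments, of which the real one had the largest share and the next 62.0%, so the smallest proportion this design allows is 1 in 4.

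**Figure D3:**
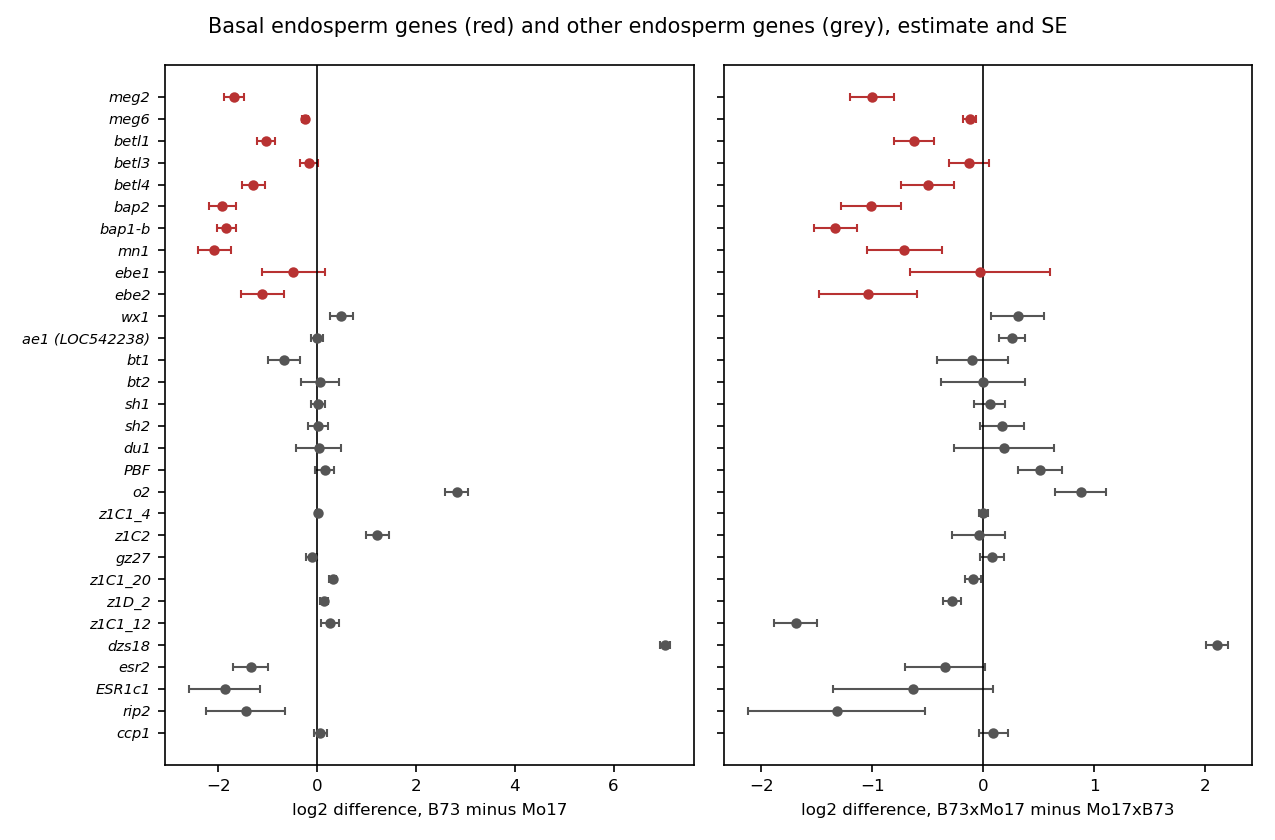
Log2 difference (horizontal axes) between B73 and Mo17 on the left and between B73xMo17 and Mo17xB73 on the right for 10 basal endosperm genes in red and the 20 other genes of the zein and endosperm lists in grey, with limma's SE as bars and n = 3 arrays per group. All 10 basal genes lie left of 0 in both panels, with medians of -1.20 and -0.66, while the other genes have medians of 0.04 and 0.03.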

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

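All tests in this part, the counts of other splits of the arrays included, were chosen after the results had been seen.

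The reciprocal hybrids, which have the same pair of nuclear genomes, differed at 153 probe sets. Each difference between the crosses named here passed limma's test of the difference itself. On the log2 scale they were 2.11 for dzs18, 1.43 for LPE1, 1.10 for fie1, 0.92 for yuc, 0.77 for glb3, 0.76 for S6K, 0.45 for plt2, 0.35 for ubc7 and 0.29 for phi1. Those lower in B73xMo17 were lox1 (-1.93), z1C1_12 (-1.69), sfp1 (-1.63), gst30 (-1.55), gst2 (-1.36), bap1-b (-1.33), bap-1a (-1.25), opr5 (-1.23), meg2 (-1.0) and opr1 (-0.99). Among the probe sets unnamed here Zm.12.1.S1_at stood at 1.45, and 4 others at -3.80, -3.70, 3.17 and 3.68. The real split of the 6 hybrid arrays was 1 of 10 splits with that many calls and the highest other gave 1. With 10 splits the share cannot fall under 0.05.

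Most of the called reciprocal differences ran toward the seed parent. Selfed or mixed kernels in the hybrid samples would move all genes that differ between the inbreds by a like share of that difference. The called probe sets had a median share of 0.844, against 0.045 over 1029 uncalled probe sets at least 4-fold apart. Of those 1029, 90.3% had an interval wholly below 0.844, so a share that large did not hold for most of them. Both sets were chosen by whether the reciprocal difference was called, which builds in a gap between them. The comparison therefore does not decide whether mixed kernels contributed to the calls. For the weaker tendency over all probe sets that differ between the inbreds, mixed kernels stay open as well, since the lowest median share over both directions and 3 dates was 0.041, above 0. Endosperm carried along with the embryos also stays open: 3 of 30 endosperm list genes were called toward the seed parent, against 16 of 1078 other genes (odds ratio 7.34, Fisher's exact two-sided p = 0.013), and endosperm holds more copies of the seed parent's genome than of the pollen parent's. The basal layer gene bap-1a, which the name search did not put in the lists, is one of those 16. A difference of the embryos themselves, such as maternal control of expression, is the biological alternative the design names, and it was not tested.

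All 10 basal endosperm genes measured higher in Mo17 than in B73, 7 of them called, with a median of -1.20 (quartiles -1.81 and -0.62; -1.34, -1.50 and -0.93 by date). Between the hybrids all 10 measured higher in Mo17xB73 with a median of -0.66 (-0.32, -1.20 and -0.74 by date), but only bap1-b and meg2 of these 10 were called, and both lost the call without the eBayes trend. The basal layer gene bap-1a, which the name search did not put in the lists, was called as well (-1.25). Its call was lost without the trend and with the floor. Whether more endosperm of every kind in those samples is the cause was not decided: the median of the 20 other genes of the zein and endosperm lists was 0.04 between the inbreds (quartiles -0.03 and 0.27), yet esr2 was called at -1.35, like the basal genes (ESR1c1 and rip2 measured -1.87 and -1.45, uncalled), zeins near the top of the scale could hide a rise, and how many of these genes the embryo itself expresses is not known here. Unequal pieces of basal endosperm left on the embryos may account for the pattern, as may a higher expression of these genes in Mo17, and neither was tested. The sets were divided after their values had been seen.

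Probe sets that differ between B73 and Mo17 may in part mark sequence differences under the probes in place of transcript levels. Whether they are the whole cause was not decided. Of 47 genes with a second probe set to a different transcript sequence 32 (68.1%, exact 95% interval 52.9% to 80.9%) shared its direction, and of 519 groups of probe sets whose IDs share a cluster number 326 (62.8%, exact interval 58.5% to 67.0%), but probe sets designed from the sequence of one line would share a direction too, and the line behind each probe set is not known here. For differences of at least 4-fold the share was 60.8% of 79 groups (exact interval 49.1% to 71.6%). In 23 of these the other probe set was called in the same direction and in 14 in the opposite one, in 2 of them by at least 4-fold. Sequence differences, as part of the cause or all of it, and true differences in level between the lines stay open.

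Other splits of the same arrays were counted for the remaining results. Between the inbreds the real split, with 6321 calls, was 1 of 10 and the highest other gave 0, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all pairs of one date, the others gave 0 as well. Chance was argued against, though not excluded, for the hybrids against B73 (2879 calls, 1 of 84 splits as large, highest other 665) and against Mo17 (4049, 1 of 84, highest other 1191). These splits did not keep the shared collection dates. For results that rest on the mid-parent or the parental range the splits decide nothing, since they mix arrays of B73 and Mo17, which differ from each other at far more probe sets than were called. They gave as many calls in 3 of 100 splits for the hybrid mean against the mid-parent (93 calls, highest other 1413), 3 of 84 for B73xMo17 (139, highest other 5174), 5 of 84 for Mo17xB73 (93, highest other 4164) and 100 of 100 outside the parental range (0 calls, highest other 189), and as many lists in 9 of 100 against the mid-parent (3 lists, highest other 4). The splits with far more calls than the real one point to a structure of the samples, namely genotype: those with the highest counts put all 3 arrays of an inbred on one side. Between the reciprocal hybrids 7 of 10 splits called as many lists (1 real, highest other 2), too few for a share under 0.05.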

How the results depend on the processing

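The values as deposited and the arithmetic list statistic were chosen after seeing the data, and the other alternatives were planned. Reversal of direction was looked for in the named calls, the called lists and the share toward the seed parent, and none of these reversed. The other called probe sets were not followed one by one. The larger side of some counts did change. Between the inbreds 2889 higher in B73 and 3432 in Mo17 became 1813 and 1150 with the values as deposited. Between the reciprocal hybrids 64 higher in B73xMo17 and 89 lower became 40 and 36 with the floor. The uncalled differences of his1a, a2 and fae1 and some uncalled list medians changed sign between scalings. Unless said otherwise, the cause of a changed value was not tested. With the values as deposited the counts were 2963 between the inbreds, 8 against the mid-parent (19 for B73xMo17 and 11 for Mo17xB73), 42 between the reciprocal hybrids, 916 against B73 and 1325 against Mo17, with a d/a share of 83.0%, 9 list shifts and 67 of 104 named calls. Median centring gave 184 against the mid-parent. Without the eBayes trend the mid-parent counts were 4, 21 for B73xMo17 and 0 for Mo17xB73, and the reciprocal count 39. Array weights gave 174 against the mid-parent and 188 for Mo17xB73. A fit of only the groups compared gave 52 for Mo17xB73 and 1 outside the parental range. The log2 mid-parent, lower than the arithmetic one by construction, gave 881 (811 for B73xMo17 and 693 for Mo17xB73), and linear values gave 147. The floor gave 76 reciprocal calls. Requiring 1.5-fold left 3766 inbred calls by construction. The d/a share was 80.6% at 2-fold, 73.6% with no minimum fold, 68.7% on the log2 scale and 82.6% without the lowest 50 percent of probe sets. Agreement between probe sets of a gene was 47.6% without the lowest 33.3 percent of probe sets and 45.2% without the lowest 50 percent. Lists called were 0 with an estimated correlation and 8 with all probe sets of a gene. Named calls were 69 without the lowest 50 percent, since fewer of them were tested.

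With the replicate number as a block lox1 lost its call between the inbreds, the mid-parent count was 153, and no other count moved by over 1.5 times (6562 between the inbreds, 187 between the reciprocal hybrids, 187 for B73xMo17 and 128 for Mo17xB73 against the mid-parent, 3137 against B73, 4327 against Mo17, 0 outside the parental range and 4 list shifts).

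Leaving out 1 array in turn gave 5383 to 6347 calls between the inbreds, 41 to 131 against the mid-parent, 43 to 152 for B73xMo17, 11 to 127 for Mo17xB73, 51 to 144 between the reciprocal hybrids, 1921 to 2950 against B73, 2987 to 4144 against Mo17, 0 to 1 outside the parental range and 4 to 8 list shifts. For B73xMo17 the counts past that factor were 88 without B73 replicate 2, 69 without Mo17 replicate 3, and 63 and 43 without its own replicates 2 and 3. For Mo17xB73 they were 38 and 56 without the same inbred arrays, and 34 and 11 without its own replicates 1 and 3. The 8 list shifts came without Mo17xB73 replicate 2. Over all alternatives, arrays left out included, 2306 values of single genes and lists kept their side of the threshold, 314 lost their call and 22 gained one. The called values among the 2306 also kept their direction, while uncalled ones were counted there whatever their sign. Of the named calls, 64 of 71 between the inbreds, 5 of 10 against the mid-parent and 7 of 23 between the reciprocal hybrids held without any single array. Under all other alternatives in which they were tested 48, 1 and 4 held, and dim probe sets were not tested where the filters left them out. Signal near the low end of the arrays limits the size of differences, and the median of all probe sets was 0.12 in the reciprocal contrast, -0.109 against the mid-parent and -0.113 against B73 with the values as deposited, and -0.12 against Mo17 with median centring.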

Other observations

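The genes in this part were picked after their values had been seen, and the tests are those of the limma fit. The alpha zein z1C1_12 differed by 0.26 between the inbreds (adjusted p = 0.33) and by -1.69 between the hybrids. The starch genes sh1 (0.01), sh2 (0.01), bt2 (0.06) and ae1 (LOC542238) (-0.01) were not called between the inbreds, nor were wx1 (0.49, adjusted p = 0.14) and bt1 (-0.67, adjusted p = 0.14). The cell wall invertase gene mn1, active in the basal endosperm, differed by -2.08 (adjusted p = 0.00028), and betl1 and betl4 by -1.03 and -1.29.

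The embryo desiccation genes dhn1 (1.09, adjusted p = 0.028) and mlg3 (1.40, adjusted p = 0.0027) were higher in B73 along with emb5 and dhn2, while the regulator vp1 (0.02, adjusted p = 0.9) was not called.

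Against the mid-parent, 3 genes that differed between the crosses were lower in B73xMo17 alone of the hybrids. For gst30 the level was 12.10 ± 0.30 in B73, 12.84 ± 0.14 in Mo17, 10.99 ± 0.46 in B73xMo17 and 12.54 ± 0.13 in Mo17xB73 (mean log2 signal ± SD, n = 3). B73xMo17 lay at -1.52 from the mid-parent for gst30 (adjusted p = 0.00117), at -1.54 for sfp1 (adjusted p = 0.00522) and at -1.38 for gst2 (adjusted p = 0.0091), and Mo17xB73 at 0.03 (adjusted p = 0.974), 0.09 (adjusted p = 0.914) and -0.02 (adjusted p = 0.986). Its means of 7.21 ± 0.56 for sfp1 and 5.78 ± 0.21 for gst2 were also below those of both inbreds, and whether a single hybrid lay outside the parental range was not tested.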
